A study of Homo sapiens with 8 samples.

How the data were processed

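Extracellular vesicle RNA of the colorectal cancer lines HT55, Car-1, MDST8 and SW1116 was measured in 8 libraries, 2 per line. Cells were grown in medium with fetal bovine serum, and vesicles were isolated by ultrafiltration and size-exclusion chromatography, per the labels' protocols. RNA was extracted with a kit for serum and plasma, and libraries were made with a stranded kit for total RNA at picogram input that depletes ribosomal cDNA, per the labels' protocols. The deposited file holds log2 values of 62756 Ensembl genes, and each column sums to 1000000 after 1 is subtracted from the power of 2, so the authors' values were read as log2(TPM + 1). Cutadapt, STAR 2.7.10a and the builds GRCh38 and hg38 are named per the submitters' processing notes; the counting tool, its annotation and its use of strand are not given in the sources used here. The test had been planned for TPM values, and the deposited values are already on the log scale with a pseudocount of 1, so they were used as they stand. Of each line's columns, one is named as replicate 1 in the labels and the other carries a mark that the labels do not use; it was taken as the line's second replicate without a number. No column was left unused.

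TPM steps gave whole reads for 52676 of 52679 genes seen in at least 2 libraries (relative tolerance 1e-06), and the other 3 were set from the annotated length. Recovered reads per library ranged from 399867 to 5665370, which limits what can be seen for genes of a few reads, and reads without molecular identifiers are not independent molecules. Recovered gene lengths equalled the exon union of GENCODE 29 for 91.9% of 15657 genes, and gene types and coordinates were taken from GENCODE 29 on GRCh38 (58300 genes matched; 62685 matched a symbol). Of genes with near-identical copies, such as histones, ribosomal protein genes, small nuclear RNA and Y RNA, values are uncertain, since the handling of reads with several matches is not given. Some named genes are not reported here.

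Genes with at least 1 TPM in at least 2 libraries were tested (50076 genes). The package limma 3.58.1 was fitted to log2(TPM + 1) with 1 mean per line, moderated with a mean trend (4 residual degrees of freedom, 7.73 with the prior). Its p-values were adjusted by the Benjamini-Hochberg method within each contrast at a threshold of 0.05. A line-specific gene differed in the same direction from each of the other 3 lines, and a gene separating a pairing was called in all 4 comparisons across the pairs. The contrast of a line against the mean of the other 3, or of a pair against the other pair, was used for gene lists and for single genes. A log2 difference on this scale understates the change of weakly expressed genes. Errors are the SD of TPM over 2 libraries or the standard error of the fitted difference.

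The 22 gene lists (mesenchymal, TGF-beta response, epithelial, intestinal lineage, WNT target, MYC target, EGFR ligands and feedback, proliferation, vesicle pathway, interferon response, hypoxia and glycolysis, cholesterol synthesis, cancer-testis, mitochondrially encoded, cytosolic ribosomal protein, replication-dependent histone, small structured RNA, nuclear retained RNA, blood and serum, leukocyte, endothelial and neuroendocrine genes) were fixed by name. They were tested with camera at a preset correlation of 0.01, and again with an estimated correlation, under which no list was called. The lists, the tests, the rule for named genes and the alternatives were fixed before the data were examined, apart from those named as added. The rule took, per line, the 10 higher and 5 lower line-specific genes with the largest smallest difference, and per pairing 10 separating genes per direction, with both libraries of each line on the same side and at least 10 TPM in the higher lines. It also took up to 4 called genes per list and the 12 markers VIM, ZEB1, FN1, CDH1, EPCAM, KRT20, CDX2, LGR5, AXIN2, CD63, CD9 and CD81. It named genes only for HT55 over all genes; for the other lines and the pairings it was applied to a fit of coding genes alone (18657 genes), added after the data were seen.

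Alternatives were upper-quartile scaling, quantile normalization, a rescaling without mitochondrial, small structured and histone RNA, a pseudocount of 0.1, no filter (56456 genes) and a mean TPM of at least 5 (19498 genes). Others were no trend, array weights, the replicate number as a block, each library left out in turn, fry, and for pairings the averaged contrast, a fit of 2 groups and line means. Coding genes alone, voom on the recovered reads, the omission of both HT55 libraries random lists matched on expression (10000 draws, 50 bins) and line means as units of the permutation test were added after the data were seen. With a library left out, the remaining one of its line was assumed to vary like the other lines. In data simulated for MDST8 against each other line (49668 genes), 69 of 100 genes changed 16-fold and 0 of 100 changed 4-fold were called line-specific, and 0 unchanged genes were. The averaged contrast called 92 and 18, with 13 unchanged genes. The simulation gave all lines the same gene means apart from the planted changes, so it lacked the shifts between the real lines. Its spread came from genes with at least 100 reads in both libraries of a line. Its numbers therefore need not hold for these libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and the package data.table (1.17.8) were used.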

Results

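RNA of extracellular vesicles, the membrane particles that cells release, was profiled in 4 human colorectal cancer lines, HT55, Car-1, MDST8 and SW1116, with 2 libraries per line. The vesicles were isolated by ultrafiltration and size-exclusion chromatography, and their total RNA was sequenced with a stranded kit for low input after removal of ribosomal cDNA. The study concerns mesenchymal colorectal cancer and vesicle cargo, with 2 lines of the consensus molecular subtype CMS2 and 2 of CMS4, the mesenchymal one. The labels used here do not say which lines are which, so each line was compared with the other 3, and all 3 ways of pairing the lines were tested under the names of their lines. Reads recovered from the deposited values numbered 1283448 and 761075 in HT55, 924582 and 2319938 in Car-1, 874071 and 5665370 in MDST8, and 1028093 and 399867 in SW1116 (replicate 1, then the second replicate), a range of 14.2 times. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

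Genes other than protein-coding ones held most of the TPM in each library. Genes annotated as rRNA or rRNA pseudogenes held 9.56% to 10.1% of TPM in HT55 and 18.0% to 55.9% in the other lines. Small nuclear RNA, the RNA of the spliceosome, held 12.3% to 19.5% in HT55 and 2.73% to 9.84% elsewhere. Protein-coding genes held 30.3% and 31.8% of TPM in HT55, 13.6% and 18.8% in Car-1, 23.0% and 43.7% in MDST8, and 14.6% and 13.3% in SW1116. Between 18786 genes (MDST8, second replicate) and 47333 genes (HT55, replicate 1) reached 1 TPM. A single read in a gene of 1 kb was 0.249 TPM in the former library and 1.01 TPM in the latter. These counts, and the filter at 1 TPM, thus partly follow the weight of a read. Libraries of one line correlated across genes with Pearson's r of 0.759 to 0.799, and libraries of different lines with 0.446 to 0.764; genes are not independent replicates.

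In MDST8 vesicles, mesenchymal transcripts were high and epithelial ones low. VIM, the intermediate filament protein vimentin (ENSG00000026025.16, chromosome 10, 17228259 to 17237593, GRCh38), was at 2505 ± 1496 TPM (SD, n = 2) against 15.6 ± 2.79 in HT55, 6.16 ± 0.789 in Car-1 and 49.6 ± 63.3 in SW1116. The log2 difference from the mean of the other 3 lines was 7.33 ± 0.93 (SE; limma, adjusted p = 0.0205). KRT19, a keratin of simple epithelia (chromosome 17, 41523617 to 41528308), was at 2.21 ± 0.0883 TPM in MDST8 and 72.4, 587 and 276 in HT55, Car-1 and SW1116 (log2 difference -6.12 ± 0.38, limma adjusted p = 0.0165). EPCAM, the epithelial adhesion molecule used to capture carcinoma cells, was at 0.130 ± 0.183 TPM against 20.3, 36.8 and 30.6 (log2 difference -4.63 ± 0.48, limma adjusted p = 0.0181). The all-gene median of MDST8 was -0.86 on the log2 scale (-0.41 with upper-quartile scaling, -0.06 with quantile normalization), and group medians are given relative to it.

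Of 36 mesenchymal genes, 12 rose and 1 fell in MDST8 (19 and 4 adjusted over the list alone). Those that rose included SNAI2, a repressor of epithelial genes (log2 difference 3.61 ± 0.56), MSN, which links actin to the membrane (3.27 ± 0.37), and ACTA2, smooth muscle actin (2.95 ± 0.62). The list's median lay 1.96 above that of all genes (camera, adjusted p = 1.06e-11; adjusted p = 0.209 with an estimated correlation). Among TGF-beta response genes, INHBA, an activin subunit, rose (log2 difference 2.52 ± 0.40), and 2 of 23 rose in all (3 rose and 1 fell adjusted over the list alone). The relative median of that list was 1.18 (camera, adjusted p = 8.07e-05; adjusted p = 0.209 with an estimated correlation). ZEB1, a transcription factor of mesenchymal cells, rose (26.3 ± 6.34 TPM, log2 difference 2.36 ± 0.37, limma adjusted p = 0.0254). FN1, fibronectin, had a log2 difference of 2.92 ± 0.83 and did not pass the test (limma, adjusted p = 0.0561; 0.00185 when coding genes alone were fitted).

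Of 32 epithelial genes, 22 fell in MDST8 (28 fell adjusted over the list alone). They included JUP, a junction protein (log2 difference -4.02 ± 0.43), KRT8, the keratin partner of KRT18 (-3.85 ± 0.43), and CDH1, E-cadherin (-2.46 ± 0.37, limma adjusted p = 0.0244). The relative median was -1.60 (camera, adjusted p = 2.23e-10; adjusted p = 0.270 with an estimated correlation). Of 26 intestinal lineage genes, 13 fell (21 adjusted over the list alone), with a relative median of -0.79 (camera, adjusted p = 6.3e-06; adjusted p = 0.291 with an estimated correlation). PHGR1, an intestinal epithelial transcript, fell by 4.12 on the log2 scale, LGALS4, a galectin of the gut lining, by 3.08, and KRT20, the keratin of differentiated enterocytes, by 2.73. CDX2, the intestinal transcription factor, had a log2 difference of -2.61 ± 0.47 (limma, adjusted p = 0.0281).

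MYC target, proliferation, ribosomal protein and histone transcripts were also more abundant in MDST8 vesicles. Of 28 MYC target genes, 14 rose (20 rose and 1 fell adjusted over the list alone), among them NPM1, nucleophosmin (log2 difference 2.80 ± 0.50). The relative median was 2.27 (camera, adjusted p = 1.2e-19; adjusted p = 0.209 with an estimated correlation). Of 28 proliferation genes, 11 rose (19 adjusted over the list alone), including PCNA, the DNA polymerase clamp (3.44 ± 0.63). Their relative median was 2.08 (camera, adjusted p = 3.12e-20; adjusted p = 0.209 with an estimated correlation). Of 76 cytosolic ribosomal protein genes, many with near-identical pseudogenes that make their values uncertain, 46 rose (66 adjusted over the list alone), with a relative median of 2.93 (camera, adjusted p = 2.56e-50; adjusted p = 0.209 with an estimated correlation). Of 41 replication-dependent histone genes, whose copies are also near-identical, 21 rose (30 adjusted over the list alone), with a relative median of 2.73 (camera, adjusted p = 1.77e-31; adjusted p = 0.209 with an estimated correlation). EGFR feedback genes had a relative median of 1.78 (camera, adjusted p = 8.07e-05; adjusted p = 0.209 with an estimated correlation), led by PHLDA1, a gene induced by growth factor signalling (4.17 ± 0.42). Cholesterol synthesis genes had 5 that rose (6 adjusted over the list alone), IDI1 among them (2.64 ± 0.47). Their relative median was 1.27 (camera, adjusted p = 9.86e-07; adjusted p = 0.270 with an estimated correlation). Among 10000 random lists of coding genes matched on expression, MYC targets stood at percentile 90.5, proliferation genes at 98.7, ribosomal protein genes at 98.99, histone genes at 99.8, EGFR feedback genes at 99.4 and cholesterol synthesis genes at 75.4. The 2 MDST8 libraries stood apart: from the first to the second, the log2 ratio was 1.55 for the median ribosomal protein gene and -1.28 for pooled olfactory receptor genes, which are silent in most tissues. Coding genes held 23.0% and 43.7% of TPM in them, and the median ratio of sense to antisense TPM over 50 gene pairs was 22.8 and 66.6.

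Vesicle pathway genes rose in MDST8 as well, 12 of 25 against 1 that fell (17 and 3 adjusted over the list alone), with a relative median of 2.36 (camera, adjusted p = 4.71e-15; adjusted p = 0.209 with an estimated correlation). ANXA5, a membrane-binding annexin, differed by 4.22 ± 0.43 on the log2 scale, RAB27B, a GTPase of vesicle secretion, by 3.22 ± 0.60, and SDCBP, syntenin, by 2.81 ± 0.54. The tetraspanin CD9, a surface protein of vesicles, was the member that fell (5.11 ± 1.00 TPM in MDST8, 48.1 ± 5.47 in HT55, log2 difference -2.51 ± 0.40, limma adjusted p = 0.0254). The tetraspanin CD63 was at 79.8 ± 63.1 TPM in MDST8 and 27.5 ± 4.09 in HT55 and did not pass the test (1.43 ± 0.50, limma adjusted p = 0.0829). Nor did CD81 (0.08 ± 0.50, limma adjusted p = 0.903), whose log2 difference turned to -0.32 with quantile normalization, to -0.31 with voom and to -0.86 without MDST8 replicate 1. Mitochondrially encoded genes had a relative median of 1.19 (camera, adjusted p = 0.00461; adjusted p = 0.445 with an estimated correlation), which turned to -0.52 with quantile normalization. That call was also lost without the second HT55 or the second MDST8 library.

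Among WNT target genes, which mark signalling through beta-catenin, 2 rose and 2 fell in MDST8 (5 and 5 adjusted over the list alone). CD44, a hyaluronan receptor, differed by 3.66 ± 0.50 and CCND1, cyclin D1, by 3.03 ± 0.46. NOTUM, a secreted WNT inhibitor, fell by 2.23, and SP5, a WNT-induced transcription factor, by 2.34. For the list, the relative median was 0.58 (camera, adjusted p = 0.0290; adjusted p = 0.351 with an estimated correlation). LGR5, a marker of intestinal stem cells, was at 0.366 ± 0.133 TPM and AXIN2, a feedback inhibitor of WNT signalling, at 8.13 ± 2.06. Neither passed the test (limma, adjusted p = 0.171 and 0.540). Of the hypoxia and glycolysis genes, 6 rose and 3 fell (7 and 4 adjusted over the list alone; relative median 0.94, camera adjusted p = 0.000413; adjusted p = 0.270 with an estimated correlation). PKM, pyruvate kinase, differed by 2.82 ± 0.39. Cancer-testis genes, normally limited to the germline, had 4 that rose, PRAME among them (2.87 ± 0.40), and 1 that fell (6 and 3 adjusted over the list alone; camera, adjusted p = 0.0186; adjusted p = 0.303 with an estimated correlation). Markers of other cell types had lower relative medians, -0.60 for blood and serum, -0.66 for leukocytes and -0.58 for endothelium (camera, adjusted p = 0.0188, 0.0141 and 0.0266; adjusted p = 0.398, 0.393 and 0.477 with an estimated correlation). Neuroendocrine, interferon and nuclear retained RNA genes were not called (relative medians -0.57, 0.45 and 0.71; camera, adjusted p = 0.859, 0.405 and 0.0649). Without the second MDST8 library the WNT target, cancer-testis, blood, leukocyte and endothelial calls were lost, and the endothelial one also ended with either scaling and without either HT55 library or the second SW1116 library. With coding genes alone the WNT target, hypoxia and glycolysis, cancer-testis and mitochondrially encoded calls ended. At a mean TPM of at least 5 the WNT target, hypoxia and glycolysis, mitochondrially encoded, blood and endothelial ones did, and without both HT55 libraries the blood and endothelial ones did.

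Under limma no gene differed in the same direction between MDST8 and each other line, and 1494 higher and 1905 lower genes did at an unadjusted p under 0.05. With coding genes alone 1396 did (1040 higher, 356 lower), and voom on recovered reads called 3590. The higher coding genes included STC1, a secreted glycoprotein, LGALS1, the galectin of mesenchymal cells, and MDM2, the regulator of p53 (log2 difference 4.48 ± 0.72, 4.28 ± 0.36 and 3.71 ± 0.45). The lower ones included SFN, an epithelial 14-3-3 protein, and KLK6, a secreted protease (-4.23 ± 0.61 and -4.07 ± 0.38). Against the mean of the other 3 lines, limma called 1744 genes higher and 4302 lower. Of the 47 genes examined singly that were called there, all 47 lost the call without either HT55 library, either Car-1 library, the second MDST8 library or SW1116 replicate 1. Of the same genes, 45 lost it without the second SW1116 library, and 3 without MDST8 replicate 1; 6 lost it with quantile normalization and 4 with upper-quartile scaling. With array weights 13 lost it, with a pseudocount of 0.1 4 and with no filter 2. The line-specific count was 1628 without MDST8 replicate 1.

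**Figure D1:**
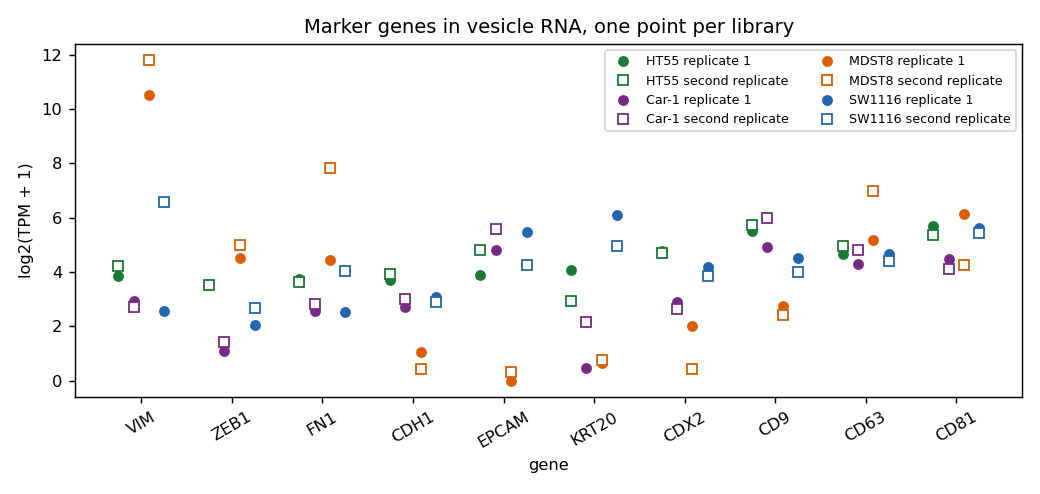
Points show log2(TPM + 1) of 10 of the 12 markers in each library, coloured by line, with filled circles for replicate 1 and open squares for the second replicate. VIM, at 2505 TPM on average, stands highest in both MDST8 libraries, and EPCAM, CDH1 and CDX2 stand lowest there.

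In HT55 vesicles, 4 coding genes that the naming rule picked among those that rose lay on chromosome 20. CTSZ, the lysosomal protease cathepsin Z (ENSG00000101160.15, chromosome 20, 58995185 to 59007247), was at 139.9 ± 22.7 TPM against 6.47, 3.23 and 5.01 in Car-1, MDST8 and SW1116 (log2 difference 4.62 ± 0.35, limma adjusted p = 0.00481). CTCFL, the testis paralog of the insulator protein CTCF, was at 52.9 ± 13.7 TPM (log2 difference 4.46 ± 0.42, limma adjusted p = 0.00649). ZBP1, a sensor of Z-form nucleic acid, was at 203 ± 34.7 (4.64 ± 0.52, limma adjusted p = 0.00798), and ZNF831, a zinc finger gene, at 88.9 ± 13.2 (5.10 ± 0.44, limma adjusted p = 0.00551). H19, an imprinted noncoding RNA on chromosome 11, was at 25.9 ± 8.73 TPM (4.62 ± 0.41, limma adjusted p = 0.00588). By Fisher's exact test (one-sided, adjusted over the chromosomes of all gene sets tested), 40 of the 221 line-specific higher genes lay on chromosome 20 (18.1% against 2.40% of tested genes, adjusted p = 1.08e-21) and 30 on chromosome 17 (13.6% against 5.01%, adjusted p = 1.77e-05). The test, here and for the other sets below, takes genes as independent draws. Coding line-specific genes of chromosome 20 lay close together, so its p-values may be too small. That set of 221 rests on every Car-1 and SW1116 library: it had 0 genes without any 1 of them, 0 with a pseudocount of 0.1 and 6 with upper-quartile scaling. With coding genes alone, 140 of 4358 lay on chromosome 20 (3.21% against 2.79%, adjusted p = 0.195), and 345 on chromosome 17 (7.92% against 5.94%, adjusted p = 2.45e-08). In that fit, chromosome 19 held 14.3% against 7.41% of tested genes (adjusted p = 2.16e-74) and chromosome 16 held 8.49% against 4.25% (adjusted p = 4.7e-47). The X chromosome, with 3.90% of tested genes, held 305 of the 4358 (adjusted p = 5.64e-28). Chromosomes 12 and 15 passed the test too (adjusted p = 2.65e-08 and 2.80e-05). Chromosome 20 also held 54 of the 1040 coding genes higher in MDST8 than in each other line (5.19%, adjusted p = 0.000142), chromosome 8 held 63 (6.06%, adjusted p = 5.16e-05), and chromosomes 11, 7 and 22 passed too (adjusted p = 0.00203, 0.00480 and 0.0276). Of the 235 coding genes higher in HT55 and MDST8 than in Car-1 and SW1116, chromosome 20 held 20 (8.51%, adjusted p = 0.000152), and chromosomes 17, 10, X and 3 passed too (adjusted p = 0.00203, 0.00695, 0.0222 and 0.0440).

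**Figure D2:**
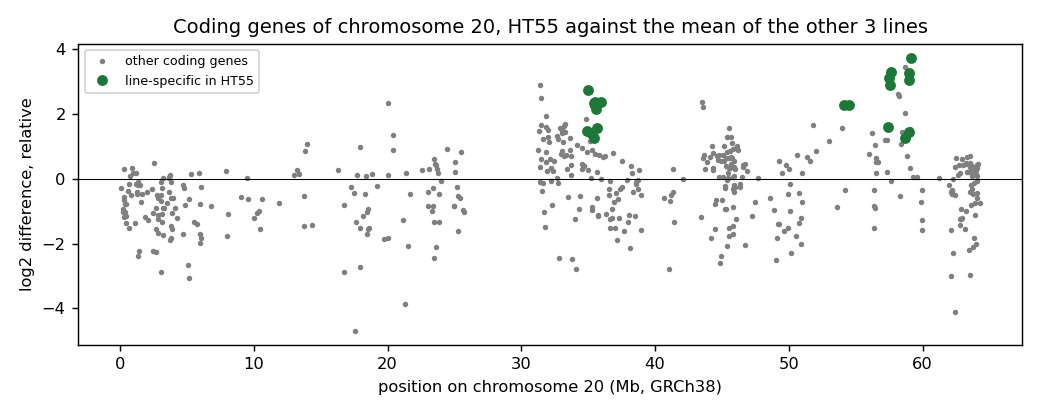
Points show the log2 difference of HT55 from the mean of the other 3 lines for coding genes along chromosome 20 (GRCh38 position), relative to the all-gene median, with line-specific genes as large points. The 349 genes that start at or beyond 30 Mb have a median of 0.19 and the 172 before it a median of -0.70; 20 line-specific genes lie in the first interval and 0 in the second.

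The all-gene median log2 difference of HT55 was 1.35 (0.24 with upper-quartile scaling, -0.01 with quantile normalization), and group medians are relative to it. In this contrast limma called 22594 of the 50076 tested genes higher and 721 lower. With coding genes alone it called 10696 of 18657 higher, so counts of genes that rose need to be read against these. Intestinal lineage genes rose, 21 of 26 (22 adjusted over the list alone), with a relative median of 0.77 (camera, adjusted p = 0.000376; adjusted p = 0.603 with an estimated correlation). Among 10000 random lists of coding genes matched on expression, intestinal genes stood at percentile 100, as did mitochondrially encoded genes, and leukocyte genes stood at 99.5. The ribosomal protein and histone lists stood at percentile 0, proliferation genes at 0.07, vesicle pathway genes at 0.61 and MYC targets at 24. PHGR1 was at 80.5 ± 2.37 TPM (log2 difference 4.35 ± 0.68), TSPAN8, a tetraspanin of gut epithelium, had a log2 difference of 2.81 ± 0.46, and LGALS4 was at 39.8 ± 6.52 (2.79 ± 0.41).

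Ribosomal protein and histone transcripts were lower in HT55 vesicles. Of 76 ribosomal protein genes, 43 fell and 1 rose (44 and 1 adjusted over the list alone), RPL9 by 2.81 and RPS21 by 2.75 on the log2 scale. Of 41 histone genes, 26 fell (28 adjusted over the list alone), H3C3 by 4.29 and H4C9 by 3.51. Copies of both families are near-identical and their values uncertain. Relative medians were -2.86 and -2.83 (camera, adjusted p = 3.85e-67 and 1.18e-53; adjusted p = 0.336 and 0.150 with an estimated correlation). The glycolytic enzyme ENO1 fell by 3.26 and GAPDH by 2.37, while the hypoxia and glycolysis list had 11 genes that rose and 5 that fell (11 and 5 adjusted over the list alone; camera, adjusted p = 0.0510). Of the MYC targets, 4 rose and 5 fell, NPM1 by 2.38 (4 and 4 adjusted over the list alone). Relative medians were -1.33 for MYC targets (camera, adjusted p = 1.61e-08; adjusted p = 0.470 with an estimated correlation), -1.49 for proliferation genes (camera, adjusted p = 1.14e-08; adjusted p = 0.408 with an estimated correlation) and -1.54 for vesicle pathway genes (camera, adjusted p = 4.7e-08; adjusted p = 0.470 with an estimated correlation). Small structured RNA genes had a relative median of -2.29 (camera, adjusted p = 5.07e-12; adjusted p = 0.150 with an estimated correlation). Mesenchymal genes lay at -0.84 (11 rose and 1 fell, 8 and 0 adjusted over the list alone; camera adjusted p = 0.00649; adjusted p = 0.603 with an estimated correlation) and cholesterol synthesis genes at -0.87 (camera adjusted p = 0.0282; adjusted p = 0.603 with an estimated correlation). The small structured call ended with quantile normalization, the mesenchymal and cholesterol ones without HT55 replicate 1 or the second MDST8 library, and the cholesterol one also without the second Car-1 library, with a pseudocount of 0.1, with no filter and at a mean TPM of at least 5.

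Lists of genes foreign to colorectal epithelium held many calls in HT55, where the all-gene median was raised, and none was called by camera relative to other genes. Of all 50076 tested genes 22594 were called higher in HT55, and 10696 of 18657 when coding genes alone were fitted. Under limma, 13 of 18 leukocyte genes rose, as did 10 of 12 endothelial genes, among them VWF of blood vessel lining (2.24 ± 0.52). So did 11 of 15 blood and serum genes, HBA1, a globin with a near-identical copy (3.41 ± 0.50), and 9 of 15 neuroendocrine genes, SYP of synaptic vesicles (3.11 ± 0.48). The camera adjusted p was 0.0767, 0.0767, 0.137 and 0.345. Adjusted over the list alone, 13, 10, 13 and 9 rose. Also not called by camera were cancer-testis (11 of 19 rose, adjusted p = 0.186), TGF-beta response (7 rose, adjusted p = 0.0510), interferon response (7 rose and 1 fell, adjusted p = 0.0510), and EGFR feedback genes (6 rose and 1 fell, adjusted p = 0.186). The same held for epithelial (11 of 32 rose, adjusted p = 0.937), nuclear retained RNA (3 rose and 1 fell of 5, adjusted p = 0.304), WNT target (11 of 20 rose and 3 fell, adjusted p = 0.796) and mitochondrially encoded genes (5 of 15 rose, adjusted p = 0.914). For the last pair of lists the relative medians were 0.10 and 0.52 while the test pointed lower. NOTUM (3.16 ± 0.45) and ASCL2, a stem cell transcription factor (2.61 ± 0.61), rose. Adjusted over the list alone, 12 cancer-testis, 7 TGF-beta, 5 interferon, 6 EGFR feedback, 10 epithelial, 3 nuclear retained, 11 WNT target and 4 mitochondrial genes rose. AXIN2 (1.65 ± 0.35, limma adjusted p = 0.0127) and LGR5 (1.58 ± 0.48, limma adjusted p = 0.0308) also passed the test, but near the all-gene shift, and not with upper-quartile scaling or quantile normalization. The same held for CD9 (48.1 ± 5.47 TPM, limma adjusted p = 0.0211), whose log2 difference turned to -0.12 with upper-quartile scaling. The median ratio of sense to antisense TPM over 50 gene pairs was 3.08 and 3.72 in HT55 and 6.73 to 66.6 in the other libraries. Olfactory receptor genes, silent in most tissues, pooled to 2.87 TPM in HT55 and 0.708 elsewhere (exact permutation test over 28 assignments of the libraries, two-sided, p = 0.0357, the smallest it can give), and per 1000000 of coding TPM to 9.25 and 4.18 (exact permutation test, p = 0.179). The pool of 372 genes included a member called higher in HT55 and MDST8 than in Car-1 and SW1116 with coding genes alone. That permutation test treats libraries of a line as independent. With line means as units there are 4 assignments, p cannot go below 0.25, and the exact permutation test gave p = 0.25 and 0.5.

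Limma called 232 genes in the same direction between HT55 and each other line, 221 higher and 11 lower, against 11800 and 143 at an unadjusted p under 0.05, 4405 with coding genes alone and 4176 by voom. Upper-quartile scaling left 7 (6 higher), a pseudocount of 0.1 left 2 (0 higher), and the rescaling without mitochondrial, small structured and histone RNA left 64. Quantile normalization gave 610, of which 239 were higher and 371 lower. The count was 103 and 108 without the first and the second HT55 library, 0 without any single library of Car-1 or SW1116, and 3641 and 2608 without the first and the second library of MDST8. Of 34 genes examined singly that were called against the mean of the other lines, 25 and 31 lost the call without the first and the second HT55 library, 16 with upper-quartile scaling, 8 with quantile normalization and 2 with a pseudocount of 0.1. In addition, 1 lost it without any 1 of the Car-1 libraries, the second MDST8 library or the second SW1116 library. Of the noncoding genes the naming rule picked, TRAJ32 and IGHD3-16 rested on 1 to 3 reads per HT55 library, and the rule also picked RNVU1-8, which has near-identical copies.

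Transcripts of the secreted proteins LCN2, MMP7 and SERPINA1 were high in Car-1 vesicles. LCN2, an iron-scavenging protein of inflamed mucosa (ENSG00000148346.12, chromosome 9, 128149071 to 128153455), was at 492 ± 352 TPM against 32.3, 2.98 and 24.3 in HT55, MDST8 and SW1116 (log2 difference 4.86 ± 0.50, limma adjusted p = 0.0406; 5.94e-06 with coding genes alone). RARRES1, a retinoid-induced gene, was at 61.2 ± 33.9 TPM (5.45 ± 0.45, limma adjusted p = 0.0254), and MMP7, an epithelial matrix protease, at 188 ± 111 (5.08 ± 0.49, limma adjusted p = 0.0387). SERPINA1, the elastase inhibitor alpha-1 antitrypsin, was at 115 ± 66.9 (4.60 ± 0.41, limma adjusted p = 0.0316), and THBS1, thrombospondin, at 98.9 ± 9.16 (3.90 ± 0.39, limma adjusted p = 0.0387). KRT17, which has near-identical pseudogenes, and KRT19 also rose (5.47 ± 0.48 and 3.86 ± 0.38, limma adjusted p = 0.0316 and 0.0387). AKAP12, a scaffold of protein kinase A, fell by 3.51 (limma, adjusted p = 0.0406).

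Epithelial genes of Car-1 had a relative median of 1.15, with 1 of 32 called (7 adjusted over the list alone; camera, adjusted p = 1.93e-10; adjusted p = 0.480 with an estimated correlation), the all-gene median being -0.08. Mesenchymal, MYC target, EGFR feedback, mitochondrially encoded and cancer-testis genes lay lower, at -0.63, -0.60, -0.77, -1.54 and -0.65 (camera, adjusted p = 0.000142, 8.56e-09, 0.000142, 3.04e-06 and 0.00148). The mesenchymal and MYC target calls ended with quantile normalization, and for each of the 5 lists adjusted p = 0.480 with an estimated correlation. WNT target, proliferation, vesicle pathway and nuclear retained RNA genes also lay lower, at -0.57, -0.56, -0.52 and -0.59 (camera, adjusted p = 0.0157, 1.26e-06, 0.0157 and 0.0476; adjusted p = 0.480, 0.480, 0.780 and 0.480 with an estimated correlation). With quantile normalization these calls ended, and the proliferation and vesicle pathway medians turned to 0.093 and 0.066. The WNT target and vesicle pathway calls also ended with coding genes alone, at a mean TPM of at least 5 and without the second Car-1 library, and the vesicle pathway one without the second MDST8 library. The nuclear retained call was lost without any 1 library but the second MDST8 one, with upper-quartile scaling and with the rescaling without mitochondrial, small structured and histone RNA. Of the 11 lists called in Car-1, 4 were lost without the second Car-1 library. Ribosomal protein genes lay at 0.41 (camera, adjusted p = 0.00442; adjusted p = 0.780 with an estimated correlation), a call lost without HT55 replicate 1, the second Car-1 library or MDST8 replicate 1, with upper-quartile scaling and with a pseudocount of 0.1, and a median that turned to -0.62 without both HT55 libraries.

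CXCL5, a neutrophil chemokine, FDCSP, a secreted mucosal peptide, and VTCN1, an immune checkpoint ligand, were called for Car-1 only with coding genes alone (limma, adjusted p = 0.000148, 8.04e-05 and 0.000555). So were the lower genes CDKN2A, the p16 cell cycle inhibitor (2.70 ± 2.29 TPM, adjusted p = 0.00519), and LYAR, a nucleolar protein (8.23 ± 3.66 TPM, adjusted p = 0.00467). No gene differed between Car-1 and each other line under limma, against 361 higher and 121 lower at an unadjusted p under 0.05, 37 with coding genes alone and 41 by voom. Against the mean of the other 3 lines 20 rose and 1 fell, and all 8 genes examined singly lost that call without any 1 library, apart from MDST8 replicate 1, without which 7 did. All 8 lost it with a pseudocount of 0.1, as did 3 with the rescaling without mitochondrial, small structured and histone RNA and 1 with upper-quartile scaling.

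In SW1116 vesicles KRT20 was at 48.8 ± 26.5 TPM against 11.1, 1.92 and 0.637 in HT55, Car-1 and MDST8 (log2 difference 3.69 ± 0.59). HPGD, which degrades prostaglandins, was at 12.8 ± 3.14 against 2.82, 1.73 and 1.51 (2.22 ± 0.40). Neither passed the test (limma, adjusted p = 0.154 and 0.178), and both did with coding genes alone (adjusted p = 0.00223 and 0.0129). So did the lower gene CDC26, a subunit of the anaphase-promoting complex (-2.47 ± 0.50, adjusted p = 0.0122). Relative to an all-gene median of -0.58 (-0.19 with upper-quartile scaling, -0.01 with quantile normalization), epithelial genes lay 0.92 higher, intestinal genes 0.38, histone genes 0.67 and small structured RNA genes 1.01 (camera, adjusted p = 1.24e-10, 0.00452, 2.25e-07 and 3.79e-05; adjusted p = 0.709, 0.961, 0.709 and 0.709 with an estimated correlation). Mesenchymal, TGF-beta response, cholesterol synthesis, cancer-testis and ribosomal protein genes lay lower, at -0.19, -0.37, -0.37, -0.24 and -0.33 (camera, adjusted p = 0.0114, 0.00452, 0.0114, 0.00999 and 0.0114; adjusted p = 0.961, 0.709, 0.974, 0.709 and 0.974 with an estimated correlation). Adjusted over the list alone, 3, 3, 2, 6 and 0 of their genes fell. These 5 calls were lost with upper-quartile scaling, all but the ribosomal protein one without SW1116 replicate 1, and all but the TGF-beta one without the second HT55 library. The ribosomal protein call also ended without the second Car-1, MDST8 or SW1116 library, and the mesenchymal one without HT55 replicate 1. Quantile normalization ended the mesenchymal and cholesterol synthesis calls, and those and the ribosomal protein one ended with coding genes alone and with the rescaling without mitochondrial, small structured and histone RNA. The mesenchymal call also ended at a mean TPM of at least 5. The intestinal and histone calls were lost without SW1116 replicate 1 and the small structured one with quantile normalization. Without both HT55 libraries the small structured and cancer-testis calls ended and the histone median turned to -0.30. Limma called no line-specific gene, against 64 higher and 385 lower at an unadjusted p under 0.05, 11 with coding genes alone and 26 by voom.

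With the lines paired as HT55 and Car-1 against MDST8 and SW1116, the keratins KRT6B and KRT16, MUC1 and WFDC2 rose in the first pair. KRT6B and KRT16, keratins of squamous and stressed epithelia, differed by 4.26 ± 0.35 and 4.28 ± 0.50 on the log2 scale (limma, adjusted p = 0.00770 and 0.0121). MUC1, a membrane mucin, differed by 3.71 ± 0.46 (limma, adjusted p = 0.0135), and WFDC2, a secreted protease inhibitor, by 2.87 ± 0.56 (limma, adjusted p = 0.0204). Of 32 epithelial genes, 19 rose (25 adjusted over the list alone), SPINT2, a protease inhibitor, and ELF3, an epithelial transcription factor, among them (2.99 ± 0.39 and 2.74 ± 0.43). The list's median lay 0.68 above the all-gene shift of 0.97 (0.31 with upper-quartile scaling, -0.03 with quantile normalization; camera, adjusted p = 0.000661; adjusted p = 0.478 with an estimated correlation). VIM fell (-4.42 ± 0.81, limma adjusted p = 0.0192). MDST8 carried most of this, as VIM was at least 6.58 higher on the log2 scale there than in each other line, SW1116 included. In the first pair 28 of 41 histone genes fell too, H4C9 (-4.11 ± 0.66) and H4C6 (-3.41 ± 0.57) among them, their copies being near-identical. Of the histone genes, 29 fell adjusted over the list alone (relative median -2.47, camera adjusted p = 1.24e-48; adjusted p = 0.181 with an estimated correlation). Mesenchymal genes went both ways, 5 rising and 6 falling (the same numbers adjusted over the list alone; relative median -0.98, camera adjusted p = 3.94e-08; adjusted p = 0.213 with an estimated correlation). Taken alone, SW1116 had epithelial genes higher and mesenchymal genes lower than the mean of the other lines, relative to all genes. That mean includes MDST8, which lay the other way on both lists, and no alternative left out both MDST8 libraries. The mesenchymal call of SW1116 also ended with either scaling, with coding genes alone and under other alternatives given above. No gene separated the pairs in all 4 line comparisons under limma, against 1514 higher and 63 lower at an unadjusted p under 0.05, 40 with coding genes alone and 43 by voom. The averaged contrast called 13267 higher and 805 lower. All 15 genes examined singly lost that call without the second Car-1 or the second SW1116 library, 7 without the second HT55 library, 5 without HT55 replicate 1, 3 without the second MDST8 library and 1 without Car-1 replicate 1. Of these genes, 3 lost it with upper-quartile scaling, 2 with quantile normalization and 2 with a pseudocount of 0.1.

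With HT55 and MDST8 against Car-1 and SW1116, BEX1, PROCR and SRPX were higher in the first pair when coding genes alone were fitted. BEX1, a signalling adaptor of neurons, differed by 3.46 ± 0.50 (limma, adjusted p = 0.000233 in that fit), PROCR, the protein C receptor, by 2.53 ± 0.43 (0.000992), and SRPX, an extracellular protein, by 2.37 ± 0.45 (0.00171). MMP7 (-4.18 ± 0.42, 1.04e-05), EZR, the membrane linker ezrin (-2.53 ± 0.30, 0.000992), and ANXA3, an annexin (-2.94 ± 0.33, 0.000187), were lower. With all genes, the averaged contrast called KRT19 alone (-4.67 ± 0.33, limma adjusted p = 0.0422), a call lost without any 1 library but MDST8 replicate 1, without the trend and with no filter on low values. Relative to a shift of 0.45 (0.02 with either scaling), epithelial genes lay at -1.44, mesenchymal genes at 0.65 and cancer-testis genes at 0.85 (camera, adjusted p = 7.75e-23, 1.04e-05 and 0.000110; adjusted p = 0.54 with an estimated correlation for each). Adjusted over the list alone, 12 epithelial genes fell, and 23 mesenchymal and 10 cancer-testis genes rose. HT55 and MDST8 did not share the first 2 shifts. Taken alone and relative to all genes, MDST8 had epithelial genes lower and mesenchymal genes higher. HT55 alone had mesenchymal genes lower, and its epithelial genes were not called. KRT19 was at least 4.50 lower on the log2 scale in MDST8 than in each other line, HT55 included. No gene separated the pairs under limma, against 572 higher and 37 lower at an unadjusted p under 0.05, 241 with coding genes alone, 182 by voom and 99 without MDST8 replicate 1.

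With HT55 and SW1116 against Car-1 and MDST8, the chemokine CXCL1 was lower in the first pair. CXCL1, a neutrophil chemokine (chromosome 4, 73869393 to 73871242), was at 3.42 ± 0.0374 TPM in HT55 and 3.08 ± 0.404 in SW1116 against 38.0 ± 2.68 in Car-1 and 40.2 ± 14.9 in MDST8 (log2 difference -3.22 ± 0.30, limma adjusted p = 0.0450). The chemokines CXCL8 and CCL2 differed by -3.60 ± 0.42 and -3.87 ± 0.46 and passed only with coding genes alone (limma, adjusted p = 0.0505 and 0.0505 over all genes, 8.55e-05 and 8.44e-05 in that fit). So did the keratins KRT20 (3.50 ± 0.51, 0.000222) and KRT23 (3.58 ± 0.43, 8.55e-05) and WWTR1, the Hippo pathway coactivator TAZ (-2.26 ± 0.34, 0.00116). Relative to a shift of 0.61 (0.08 with upper-quartile scaling, 0.03 with quantile normalization), intestinal and epithelial genes lay higher at 0.76 and 0.64 (camera, adjusted p = 2.18e-07 and 8.59e-05; adjusted p = 0.348 and 0.580 with an estimated correlation). Ribosomal protein, histone and vesicle pathway genes lay lower at -2.44, -1.70 and -1.29 (camera, adjusted p = 4.14e-60, 1.87e-29 and 2.17e-09; adjusted p = 0.348 for each with an estimated correlation). Adjusted over the list alone, 18 intestinal and 18 epithelial genes rose and 66 ribosomal protein and 24 histone genes fell. The averaged contrast called 5 higher genes (MIR4421, RNU1-24P, MIR6126, MIR501 and ENSG00000227297) and 5 lower ones (CXCL1, ANXA2P2, SNORD71, PPIAP22 and a Y RNA copy), named after their values were seen. The CXCL1 call was lost with upper-quartile scaling, without the trend, with no filter on low values and without any 1 library but MDST8 replicate 1. No gene separated the pairs under limma, against 201 higher and 76 lower at an unadjusted p under 0.05, 10 with coding genes alone and 42 by voom.

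**Figure D3:**
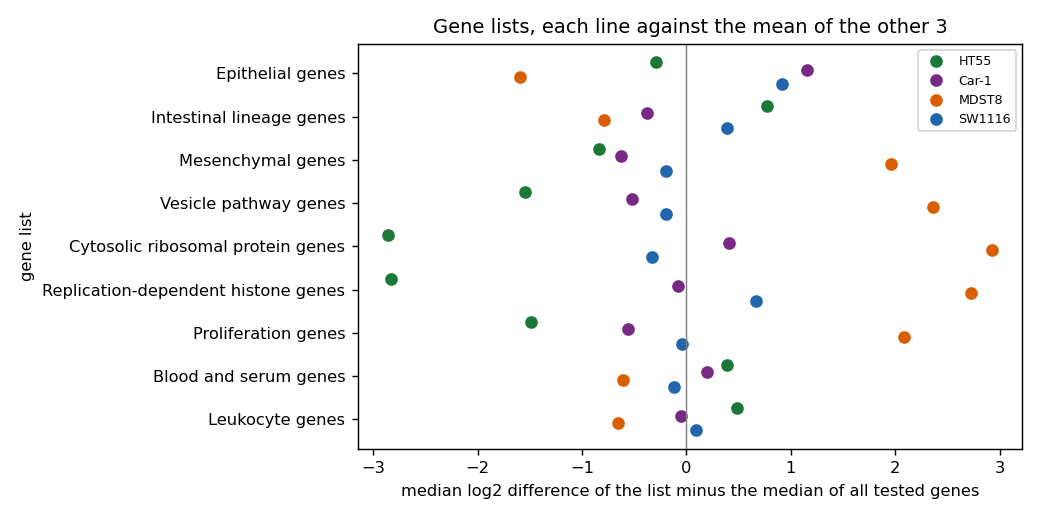
Points show, for 9 of the 22 gene lists, the median log2 difference of each line from the mean of the other 3, relative to that of all tested genes. Ribosomal protein genes range from -2.86 in HT55 to 2.93 in MDST8; with quantile normalization the proliferation and vesicle pathway points of Car-1 turn to 0.093 and 0.066, and without HT55 the ribosomal protein point of Car-1 turns to -0.62 and the histone point of SW1116 to -0.30.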

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

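The tests with coding genes alone, with voom on recovered reads and without both HT55 libraries were chosen only after the results were seen. Of the values for lists under all alternatives, 1525 kept direction and side of the threshold, 239 kept only the direction and 11 turned; for single genes the numbers were 1862, 608 and 7, and 119 newly passed. Limma's count of HT55-specific genes was 232, and that of the other lines and of the genes separating each pairing was 0. Lists called were 9 in HT55, 11 in Car-1, 19 in MDST8, 9 in SW1116, and 15, 12 and 13 in the pairings of HT55 with Car-1, with MDST8 and with SW1116. Depth limited genes of few reads, down to 399867 reads in a library.

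A pseudocount of 0.1 gave 2 HT55-specific (0 higher) and 39 MDST8-specific genes. A mean TPM of at least 5 gave 1208 for HT55, 6 for Car-1, 534 for MDST8, 3 for SW1116, 17 separating HT55 and Car-1 and 27 separating HT55 and MDST8, where fewer genes were tested. Upper-quartile scaling gave 7 for HT55, with 14 lists called in HT55 and 4 in SW1116. Quantile normalization gave 610 for HT55 (239 higher, 371 lower), 23 for Car-1, 26 for MDST8, and 14, 8 and 1 separating the pairings of HT55 with Car-1, MDST8 and SW1116, with 7 lists called in the pairing of HT55 with MDST8. Rescaling without mitochondrial, small structured and histone RNA gave 64 for HT55, 1 for MDST8 and 4 lists in SW1116, and array weights gave 3979 for HT55, 6 for Car-1 and 6 separating HT55 and Car-1. The cause of these changes was not tested.

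Coding genes alone gave 4405 for HT55, 37 for Car-1, 1396 for MDST8, 11 for SW1116, and 40, 241 and 10 for the pairings, with 5 lists in SW1116; fewer genes were tested. voom gave 4176, 41, 3590 and 26 for the lines and 43, 182 and 42 for the pairings, with 17 lists in HT55. For the pairings, the averaged contrast gave 14072, 1 and 10, the fit of 2 groups 738, 0 and 7, and line means 5, 0 and 0. An estimated correlation left 0 lists in all 7 contrasts, and fry called 0 in Car-1, 12 in MDST8 (7 higher, 5 lower; camera 14 and 5), 0 in SW1116 and 0 in the pairing of HT55 with SW1116. In HT55 fry called 12 lists, 10 higher and 2 lower, where camera called 1 higher and 8 lower; fry does not compare a list with other genes.

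With libraries left out in turn, HT55-specific genes ranged from 0 (without either library of Car-1 or of SW1116) to 3641 (without MDST8 replicate 1), MDST8-specific genes from 0 to 1628 (without MDST8 replicate 1) and genes separating HT55 and MDST8 from 0 to 99 (without MDST8 replicate 1). Lists called ranged from 7 to 14 in HT55, 7 to 12 in Car-1, 14 to 20 in MDST8, 3 to 10 in SW1116, and 14 to 19, 10 to 14 and 11 to 15 in the pairings. SW1116 lists fell to 3 without SW1116 replicate 1. The cause was not tested, apart from the MDST8-specific count without MDST8 replicate 1, which was 2924 with the second library thinned, so depth is argued against there.

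The replicate number as a block left 0 HT55-specific genes and 16, 12 and 13 lists in the pairings, and 1 of the 11 lists called in Car-1 was lost. With the block, all 8 single genes called in Car-1 lost the call, as did 4 of 47 in MDST8, 1 of 34 in HT55, KRT19 in the pairing of HT55 with MDST8 and CXCL1 in that of HT55 with SW1116. The numbers showed no pairing of the samples: differences between replicates correlated between lines with r from -0.0982 to 0.0894 across genes.

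Quantile normalization turned the medians of proliferation (0.093) and vesicle pathway genes (0.066) in Car-1, of mitochondrially encoded (-0.52) and small structured RNA genes (-0.31) in MDST8, of mitochondrially encoded genes in the pairing of HT55 with Car-1 (0.55), and of MYC target (-0.10), proliferation (-0.10), vesicle pathway (-0.22) and cholesterol synthesis genes (-0.16) in that of HT55 with MDST8. It also turned CD81 (-0.32), LGR5 (0.18) and AXIN2 (0.0016) in MDST8. Upper-quartile scaling put AXIN2 at 0.66 in MDST8 and CD9 at -0.12 in HT55. CD81 in MDST8 was at -0.31 with voom and, with libraries left out in turn, from -0.86 (without MDST8 replicate 1) to 1.03 (without the second MDST8 library). Without both HT55 libraries, ribosomal protein genes of Car-1 lay at -0.62 and histone genes of SW1116 at -0.30. The cause was not tested.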

Other observations

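The test of copy number, that of one scaling factor, that of background shares, those of mitochondrial DNA and of light-strand RNA, and the counts over other splits of the samples were chosen only after the results were seen.

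Small structured RNA moved apart in the vesicles. RMRP, the RNA of a ribosomal RNA processing enzyme, was at 36131 ± 3142 TPM (SD, n = 2) in MDST8 against 3492 in HT55, 3459 in Car-1 and 12597 in SW1116 (log2 difference 2.76 ± 0.57, limma adjusted p = 0.0335). VTRNA1-1, a vault RNA, was at 3530.2 ± 834 against 17337, 17048 and 114400 (-3.08 ± 0.80, limma adjusted p = 0.0480). MALAT1, a nuclear retained RNA, rose in MDST8 (2.36 ± 0.47, limma adjusted p = 0.0320). RNY1, a Y RNA with near-identical copies elsewhere in the genome, was higher in HT55 and Car-1 than in MDST8 and SW1116 (2.57 ± 0.46, limma adjusted p = 0.0188). The small structured list had 5 genes that rose and 1 that fell in MDST8 (5 and 3 adjusted over the list alone), with a relative median of 1.15 (camera, adjusted p = 0.00330; adjusted p = 0.270 with an estimated correlation) that turned to -0.31 with quantile normalization. That call also ended at a mean TPM of at least 5 and without both HT55 libraries.

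HT55 libraries held more TPM over most genes, and 18.1% of its 221 line-specific higher genes lay on chromosome 20, against 3.21% of 4358 when coding genes alone were fitted (2.79% of those tested). Library depth is argued against by the all-gene median, which was 1.27 after thinning to the shallowest library and 1.35 before. One scaling factor from fewer small structured RNA reads would raise all other genes alike, while ribosomal protein genes had a median of -1.50. Genomic DNA reads or RNA that follow copy number remain a candidate explanation. Over 468 bins of 5 Mb, the deviation of HT55 from the other lines correlated with r = 0.547 after GC between separate genes and separate HT55 libraries. The same measure gave 0.647 in Car-1, 0.233 in MDST8 and 0.213 in SW1116. Both sides shared the libraries of the other lines, so r cannot tell a deviation of HT55 from one of those libraries. Before GC was removed, r was 0.598 in HT55, against -0.292 to 0.127 between lines. Between lines, each line was part of the other's reference, so that range is not a like comparison. The genes were weakly expressed ones, chosen after a first version with another threshold. The 20 coding line-specific genes of chromosome 20 started between 34872146 and 35954564 or between 54153449 and 59123381, a focal excess that the median of that chromosome's 7 bins (-0.278, rank 19 of 22) does not test, and its source stays open.

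The number of MDST8-specific genes depended on the first MDST8 library: it was 0 over all libraries and rose without that library. The greater depth of the second library is argued against as the source. Without the first library, the number rose further when the second was thinned to the reads of the first. It thus still changed with depth. The share of background reads could differ between the libraries: olfactory receptor genes, silent in most tissues, had a log2 ratio of -1.28 of the second to the first library, and ribosomal protein genes one of 1.55. The olfactory pool included a gene called higher in HT55 and MDST8 than in Car-1 and SW1116 with coding genes alone, so it is not purely background. The spread between the MDST8 libraries gave 25.4% of the summed within-line variance, where the lines ranged from 21.7% in Car-1 to 29.2% in HT55. Leaving out either MDST8 library removes that spread from the shared variance. By itself it therefore cannot explain why the calls differed between these omissions. No biological explanation was tested.

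MT-ND6, the sole protein gene of the light strand of mitochondrial DNA, exceeded the heavy-strand gene MT-ND5 in every library, by 2.22 to 86.5 times. Mitochondrial DNA reads without strand would cover both genes alike, yet the ratio was above 5 in 7 of the 8 libraries. Counting on the opposite strand predicted more antisense than sense TPM, and the lowest median sense to antisense ratio over 50 gene pairs was 3.08. The pairs were those with the most abundant sense gene by measured TPM. That choice itself raises the ratio, so the test cannot exclude counting on the opposite strand. Light-strand precursor RNA stays open: light-strand tRNA genes exceeded heavy-strand ones in 4 of 8 libraries, by at least 2.41 times, and those 4 had the highest MT-ND6 ratios (54.1 to 86.5, against 2.22 to 26.8). The other 4 libraries had more heavy-strand tRNA in pooled TPM, with light to heavy ratios of 0.179 to 0.957. The pools held 8 light-strand and 14 heavy-strand genes. A pooled ratio under 1 therefore does not show less light-strand RNA per gene, and the source of the excess is not settled.

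Over the 35 splits of the 8 libraries into 4 and 4, the fit of 2 groups called 738 genes for HT55 and Car-1 against MDST8 and SW1116. Only 1 split, this one itself, gave as many, the highest other being 151. For HT55 and MDST8 against Car-1 and SW1116 it called 0, which all 35 reach by definition, the highest other giving 738. At an unadjusted p under 0.05 it called 3287, 10 of the 35 gave as many and the highest other gave 15017. For HT55 and SW1116 against Car-1 and MDST8 it called 7, 5 gave as many and the highest other gave 738. Only these 3 splits keep both libraries of each line together, and libraries of a line are alike, so the count of 738 does not exclude chance between lines, and line means called 5 genes. Nor is chance excluded for the counts of 3287 and 7.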
